A study of Mus musculus with 14 samples.

How the data were processed

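The study measured mRNA, small RNA and AGO2 binding in mouse bone marrow derived macrophages, which are macrophages grown from marrow in medium conditioned by L929 cells, a fibroblast line that secretes the growth factor CSF1. Per the labels' protocols the culture held 20% L929 medium for 6 days, whereas the series design text gives 7 days of culture, and the difference could not be settled. Cells labelled wild type carried the floxed Elavl1 allele without Cre, and cells labelled knockout carried it with LysM-Cre, a recombinase placed in the Lyz2 gene. The 14 libraries were 4 wild type and 4 knockout mRNA libraries (numbers 1 to 4 in each genotype), small RNA libraries of wild type 1 and 2 and of knockout 3 and 4, and 1 AGO2 PAR-CLIP library per genotype. Nothing in the labels ties a number to a mouse or a day, beyond the series design text calling the mRNA samples biological repeats.

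The authors deposited, per the file headers, a read count and an RPKM value for each of 21444 Ensembl genes in each mRNA library. The counts as deposited were used for every test and the RPKM values deposited beside them were not used. For small RNA the deposited values were read counts of 485 mature miRNAs, each listed with at least 1 read in every library. That list holds no miRNA with a count of 0, so it may have been filtered on detection. The small RNA file of KO 4 names KO 4 over its counts but KO 2 over the fractions beside them. The library is taken as its sample record labels it. If it were KO 2 it would share number 2 with WT 2, and genotype would be only partly confounded with the number sets, which could not be settled. For PAR-CLIP the deposited tables list binding groups, which are clusters of overlapping reads, with a position, strand, sequence, read count, number of T-to-C conversion locations, conversion event count, annotation class, transcript and gene name. In PAR-CLIP cells take up 4-thiouridine, and crosslinked uridines are read as C, so a conversion marks crosslinked RNA. Each group held at least 5 reads. CASAVA 1.8.2, Bowtie 0.12.7 and the mouse build mm9 are named in the submitters' processing notes. The gene counter, its treatment of strand and of reads that map more than once, and the program that made the groups are not given in the sources used here. Coordinates are printed as the PAR-CLIP tables give them, on mm9. In all groups the length equalled end minus start plus 1, and whether the first base of a chromosome counts as 0 or 1 could not be settled without a genome sequence.

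Gene symbols came from a table pairing Ensembl identifiers with names, which matched 19328 of the 21444 identifiers. Among those symbols 10952 of the 12034 gene names given for PAR-CLIP groups were found. Total counts per mRNA library ran from 8160789 to 25030262 and per small RNA library from 6886110 to 10265453. The PAR-CLIP groups held 6287870 reads in wild type and 6445262 in knockout, which are reads inside listed groups and not the full library depth. Reads carry no molecular identifiers, so binomial intervals cover counting error only. All intervals of shares are exact Clopper-Pearson at 95%. Intervals of ratios of group numbers treat each number as a Poisson count.

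Knockout was compared with wild type by edgeR 4.0.16 quasi-likelihood tests (R 4.3.3) with TMM scaling, the filterByExpr filter, genotype alone in the design and Benjamini-Hochberg adjusted p under 0.05. The filter left 14019 genes and 369 miRNAs. CPM values are scaled by TMM. DESeq2 1.42.0 was an alternative. The 27 fixed gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests each list on its own. Group tables were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and overlaps on the same strand were found with bedtools 2.31.1. Seed matches were 7mers (bases 2 to 8 of the miRNA, or 2 to 7 followed by an A) to 30 families of the macrophage list and 9 control families, each set beside 10 shuffles of the group sequences that keep dinucleotide counts. Gene sets with 3′ UTR groups in both genotypes or in a single genotype were tested on the mRNA counts with camera, and their medians were placed among 10000 random lists matched on expression.

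Whether equal numbers pair the mRNA libraries was tested on the counts. Deviations of wild type and knockout libraries with the same number from their group means correlated at 0.770, 0.810, 0.745 and 0.801 for numbers 1 to 4, all above the minimum of 0.1, so the replicate number was fitted as a block. Libraries of unequal number correlated as well or better within numbers 3 and 4, at 0.832 for WT 4 with KO 3 and 0.764 for WT 3 with KO 4. For numbers 3 and 4 the values therefore show the number set and not the pairs. Within numbers 1 and 2 libraries of unequal number correlated less, at 0.241 for WT 1 with KO 2 and 0.344 for WT 2 with KO 1. These values also exceed 0.1, so the minimum does not part pairs from number sets. No label states a pairing. The first principal component held 65.0% of the variance and parted numbers 1 and 2 from numbers 3 and 4 in both genotypes. No block could be fitted to the small RNA libraries, whose wild type and knockout samples share no number in the sample records.

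The steps were tested on simulated data. With 200 of 14019 genes changed, the mRNA test without the block called 0 of 67 genes changed 1.5-fold, 8.96% of those changed 2-fold and 69.7% of those changed 4-fold, and it called 0 unchanged genes. With the replicate number as a block it called 70.1%, 89.6% and 97.0%, and 7.57% of its calls were unchanged genes. The simulated counts were drawn with an effect of the replicate number and the spread of the blocked fit. The gain from the block was thus built in and does not show that the real libraries are paired. With 40 of 369 miRNAs changed, the small RNA test called 70.0% of those changed 2-fold and 100% of those changed 4-fold, with 2.86% of its calls unchanged. These simulated libraries held no difference between number sets, unlike the real comparison. The shuffles kept all dinucleotide counts, and 100% of seed matches planted in 20000 simulated groups were found.

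A rule for naming genes was fixed, like the groups, the lists and the main tests, before the data were examined. It names the genes Elavl1, Elavl2, Elavl3, Elavl4, Lyz2, Zfp36 and Tnf always, the 5 genes of smallest p where fewer than 8 pass, list members past the threshold, a fixed set of miRNAs with the 5 largest rises and falls among those that pass, the 5 PAR-CLIP genes with most group reads per genotype, the groups of Zfp36 and Elavl1, and the 5 largest rises and falls in group reads among genes with at least 50 reads. Genes called only with the block, without a pair, with numbers 3 and 4 alone or in other fits, list members given as examples or called over their list alone, the other miRNAs that passed, the Y-linked genes and the chromosome 17 cluster were named after their values were seen. For ranking changes in group reads 5 reads were added to both sides, a choice made after the data were seen. Reads of AGO2-bound miRNAs were taken from groups whose sequence holds bases 2 to 18 of 1 of 20 mature miRNAs. Those sequences, like the seeds, were written from general knowledge and were not checked against a reference, and 1 of them (miR-24-3p) was found in no group. Reads that map more than once may also be missing from the groups, so this absence does not show a lack of AGO2 binding. miR-27a-3p and miR-27b-3p share the matched bases, as do miR-23a-3p and miR-23b-3p, and let-7a-5p and let-7c-5p. Alternatives were other scaling, filters and tests, the replicate block, leaving out each library, numbers 1 and 2 or 3 and 4 alone, and for PAR-CLIP other minimums of reads, overlap, conversion and seed length.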

Results

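The series asks how the RNA-binding protein ELAVL1 (HuR) bears on miRNA binding across the macrophage transcriptome. Total RNA gave 4 mRNA libraries per genotype, with 14585778, 11192104, 24681273 and 24181994 counts in the libraries labelled wild type (WT 1 to 4) and 8160789, 19547964, 22920606 and 25030262 in those labelled knockout (KO 1 to 4). Small RNA libraries held 7869443 and 6886110 miRNA counts (WT 1 and 2) and 7207333 and 10265453 (KO 3 and 4). AGO2 PAR-CLIP, which crosslinks and precipitates RNA held by the miRNA effector AGO2, gave 66451 binding groups in wild type and 85458 in knockout from 1 library each. The labels do not say that repeats came from separate animals, so p-values measure the spread between these samples.

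Elavl1 mRNA (ENSMUSG00000040028), the target of the knockout, was not lower in the libraries labelled knockout. It stood at 63.5 ± 2.00 CPM (SD, n = 4) in wild type and 69.5 ± 6.13 CPM (n = 4) in knockout, and it was higher in the knockout library of all 4 number pairs. The log2 fold change was 0.13 (SE 0.13, edgeR adjusted p = 0.9999). The counts cover the whole gene, so they cannot show whether the floxed part was lost, and genotypes below are those of the labels. Elavl2, Elavl3 and Elavl4, the neuronal relatives of Elavl1, had at most 0.137 CPM in any library and were not tested.

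Lyz2, the lysozyme gene that carries the LysM-Cre insertion, stood at 12428 ± 2555 CPM (SD, n = 4) in wild type and 5067 ± 1004 CPM in knockout. Its paralog Lyz1 stood at 1672 ± 364 and 686 ± 139 CPM. All 4 knockout libraries lay below all 4 wild type libraries for both genes, whose log2 fold changes were -1.29 (SE 0.23) and -1.28 (SE 0.22). The copies are so alike that reads could be shared between them, and Lyz1 values are uncertain for that reason. Only the libraries labelled knockout carry the LysM-Cre insertion. Its effect, on Lyz2 or on other genes, therefore cannot be told apart from that of a loss of ELAVL1. Zfp36, which encodes the mRNA decay factor tristetraprolin, had 151 ± 28.7 CPM in wild type and 194 ± 46.0 CPM in knockout, a log2 fold change of 0.36 (SE 0.21). That value was 0.20 without KO 4 and 0.50 without WT 4. Tnf had 71.4 ± 18.2 and 67.8 ± 21.4 CPM, a log2 fold change of -0.08 (SE 0.26). The other genes of smallest p were Mycbpap at 1.72 (SE 0.38), from under 1 CPM in every library, Plac8 at 1.74 (SE 0.39) and Tep1, a telomerase-associated protein gene, at -0.61 (SE 0.14).

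**Figure D1:**
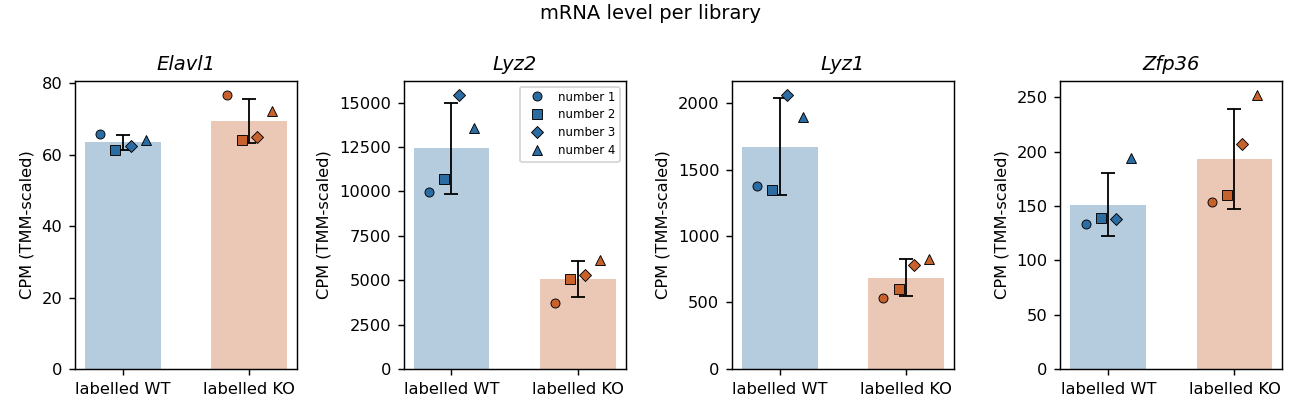
TMM-scaled CPM (y axis) of Elavl1, Lyz2, Lyz1 and Zfp36 in the mRNA libraries labelled wild type and knockout. Points are libraries by number, bars are means and error bars are the SD of 4 libraries. Lyz2 lies between 3722 and 6142 CPM in knockout and between 9949 and 15451 CPM in wild type, while Elavl1 shows no lower level in knockout.

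None of these genes passed the edgeR threshold without the replicate block (all at an edgeR adjusted p of 0.9999): 0 of 14019 genes passed, with 81 at an unadjusted p under 0.05. That is fewer than a threshold of 0.05 gives without any difference. The test without the block was therefore conservative, and its count of 0 does not show a lack of change. DESeq2 called 3 genes, Lyz2, Lyz1 and Tep1, all lower in knockout. With the replicate number as a block, which compares each knockout library with the wild type library of its number, edgeR called 5 genes. In that fit 1321 of 14019 genes had an unadjusted p under 0.05. Lyz1 fell by 1.28 (SE 0.08, adjusted p = 8.6e-05) and Lyz2 fell by 1.29 (SE 0.10, adjusted p = 0.000472) on the log2 scale. Cxcl2, a neutrophil chemokine, fell by 1.41 (SE 0.18, adjusted p = 0.0213), and Abcb4, a phospholipid transporter, fell by 0.91 (SE 0.11, adjusted p = 0.0204). Mmp9, a matrix metalloproteinase, rose by 0.94 (SE 0.11, adjusted p = 0.0152), with 118 CPM in KO 1 and 15.2 to 28.8 CPM in the other knockout libraries, and 58.5 CPM in WT 1 against 7.65 to 19.4 in the other wild type libraries. Zfp36 had a blocked log2 fold change of 0.35 (SE 0.08, adjusted p = 0.202) and did not pass. Blocked DESeq2 called 82 genes, 35 higher and 47 lower, and the blocked edgeR count was 29 without pair 2 and 3 without pair 4. Without pair 1 the calls of Mmp9 (adjusted p = 0.164), Abcb4 (adjusted p = 0.115) and Cxcl2 (adjusted p = 0.164) ended, and 4 genes were called, Lyz1, Lyz2, Slc7a11 and Srxn1. Without pair 4 Mmp9 (adjusted p = 0.0630) and Cxcl2 (adjusted p = 0.0526) ended too. With the sets of numbers 1 and 2 and of 3 and 4 as the block, Lyz1 alone passed (edgeR adjusted p = 0.00407), and Lyz2 did not (adjusted p = 0.0588). The genes called with the block alone were named after their values were seen.

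The libraries differed far more by number than by genotype. Between numbers 3 and 4 and numbers 1 and 2, with genotype in the fit, edgeR called 7181 genes, 3582 higher and 3599 lower. No gene passed for a difference of the genotype effect between those number sets (0 of 14019 by edgeR, with 0.949% of genes at an unadjusted p under 0.05). That share is below what a threshold of 0.05 gives without any difference. The test was therefore conservative and does not show equal effects in the number sets. With numbers 3 and 4 alone edgeR called 14 genes, 8 higher and 6 lower in knockout, and with numbers 1 and 2 alone it called 0, with 17 at an unadjusted p under 0.05. Of the 13215 genes tested with numbers 1 and 2 alone, 17 is again fewer than that threshold gives without any difference. The counts of 14 and 0 therefore do not show that the effect was limited to numbers 3 and 4. Ly6a, a surface antigen gene, rose by 2.43 (SE 0.23) with numbers 3 and 4 alone and the cystine transporter gene Slc7a11 fell by 1.66 (SE 0.12).

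Without the block, interferon-response genes were slightly higher and cell cycle genes slightly lower in the libraries labelled knockout, and both calls ended without 1 library and with numbers 1 and 2 alone. Of 34 type I interferon response genes 33 were higher, with a median log2 fold change of 0.20 (camera adjusted p = 6.8e-10, and adjusted p = 0.310 with an estimated correlation). Irf7, the interferon-induced transcription factor, had a log2 fold change of 0.59 (SE 0.26). Of 46 cell cycle genes 38 were lower, with a median of -0.16 (camera adjusted p = 1.1e-06, and 0.434 as the adjusted p with an estimated correlation). Of 29 inflammatory cytokines and mediators 23 were lower, with a median of -0.17 (camera adjusted p = 0.000791, and 0.293 as the adjusted p with an estimated correlation), among them Nos2, inducible nitric oxide synthase, at 6.51 ± 2.40 and 3.23 ± 1.97 CPM. The interferon list had an adjusted p of 1.3e-31 with numbers 3 and 4 alone, 0.922 with numbers 1 and 2 alone and 0.0504 without WT 2. The cell cycle list had 0.115 as its adjusted p with numbers 1 and 2 alone and 0.497 without WT 1. The inflammatory list had 0.119 as its adjusted p with numbers 3 and 4 alone, 0.162 without WT 1 and 0.498 without KO 2. The fits without 1 library held no block, so they also unbalanced the number sets. With the replicate block and all libraries the camera adjusted p was 1.9e-11 for the interferon list. It was 3.7e-07 for the cell cycle list and 5.5e-06 for the inflammatory list. With the block and an estimated correlation it was 0.373 for each. Whether list changes differed between the number sets was not tested.

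Further lists differed by smaller amounts, and each call ended without 1 or more single libraries. Of 35 hypoxia and glycolysis genes 28 were lower (median -0.14, camera adjusted p = 0.00252, adjusted p = 0.293 with an estimated correlation). Of 36 reported ELAVL1 target mRNAs 25 were lower (median -0.10, camera adjusted p = 0.00569, adjusted p = 0.276 with an estimated correlation). The angiogenic factor gene Vegfa, a member of both, had 79.0 ± 41.9 CPM in wild type and 56.0 ± 29.2 CPM in knockout. Of 27 stress and unfolded protein response genes 15 were lower (median -0.06, camera adjusted p = 0.0160, adjusted p = 0.276 with an estimated correlation), led by the antioxidant genes Slc7a11 at -1.34 (SE 0.62) and Nqo1 at -1.15 (SE 0.58). Of 28 immediate early genes 19 were higher (median 0.12, camera adjusted p = 0.0186, adjusted p = 0.293 with an estimated correlation), and of 38 lysosome genes 27 were higher (median 0.07, camera adjusted p = 0.0226, adjusted p = 0.604 with an estimated correlation). The adjusted p of the hypoxia list was 0.591 without WT 2 and 0.105 without KO 3, and that of the ELAVL1 targets was 0.0571 without WT 3, 0.0607 without KO 2 and 0.156 with numbers 1 and 2 alone. The stress list had an adjusted p of 0.579 without WT 2, 0.291 without KO 3, 0.314 without KO 4 and 0.631 with numbers 1 and 2 alone. The lysosome list had an adjusted p of 0.927 without WT 1, 0.0528 without WT 2, 0.668 without KO 3, 0.455 without KO 4, 0.0666 with no filter and 0.633 with numbers 1 and 2 alone. The immediate early list had an adjusted p of 0.143 without WT 1, 0.403 without WT 3, 0.108 without KO 2, 0.105 without KO 3, 0.349 without KO 4 and 0.823 with numbers 1 and 2 alone. Here too the fits without 1 library held no block and unbalanced the number sets. With the block and all libraries the camera adjusted p was 0.000359 for hypoxia and 0.00474 for ELAVL1 targets. It was 0.00995 for stress, 0.00729 for lysosome and 0.00840 for immediate early genes, and 0.373 for each with the block and an estimated correlation.

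Of 9 lists of markers of other marrow cells 4 were called higher in the libraries labelled knockout, those of neutrophils, mast cells, stromal cells and endothelial cells, and 0 with an estimated correlation. All 16 measured fibroblast or stromal genes were higher without the block (Lox at 0.07, and -0.07 with the block), with a median log2 fold change of 0.97 (camera adjusted p = 0.00440, adjusted p = 0.629 with an estimated correlation). Col1a1, a collagen chain, had 2.59 ± 2.92 CPM in wild type and 8.30 ± 9.26 CPM in knockout. The same list had a median log2 difference of 3.44 between numbers 3 and 4 and numbers 1 and 2, with 15 of 16 genes higher. The stromal call ended without WT 1 (adjusted p = 0.232), WT 2 (adjusted p = 0.579) and KO 3 (adjusted p = 0.668), and without KO 4 the direction was lower (adjusted p = 0.846). These fits held no block, so leaving out a library also unbalanced the number sets. With numbers 1 and 2 alone it was called lower over 7 genes (camera adjusted p = 0.0333, adjusted p = 0.863 with an estimated correlation), and with numbers 3 and 4 alone higher over 17 genes (camera adjusted p = 4.2e-09, adjusted p = 0.503 with an estimated correlation), a difference that was not tested. Neutrophil and granulocyte precursor genes were higher in 10 of 12 (median 0.44, camera adjusted p = 2.0e-05, adjusted p = 0.293 with an estimated correlation), mast cell or basophil genes in 5 of 5 (median 0.41, camera adjusted p = 0.00595, adjusted p = 0.495 with an estimated correlation) and endothelial genes in 6 of 8 (median 0.31, camera adjusted p = 0.0434, adjusted p = 0.293 with an estimated correlation). The neutrophil call ended without WT 1 (adjusted p = 0.226) and with numbers 3 and 4 alone (adjusted p = 0.0979). The mast cell call ended without WT 1 (adjusted p = 0.379), WT 2 (0.579), KO 3 (0.633) and KO 4 (0.455), with no filter (0.159) and with numbers 1 and 2 alone (0.0521, 2 genes tested). The endothelial call ended without WT 1 (adjusted p = 0.0565), WT 2 (0.579), WT 3 (0.110), KO 3 (0.668) and KO 4 (0.509), and with numbers 1 and 2 alone its direction was lower (0.631). The fits of these lists without 1 library likewise held no block. With the block and all libraries the camera adjusted p was 9.6e-05 for neutrophil, 0.0148 for mast cell and 0.0250 for endothelial genes. It was 0.373 for each with the block and an estimated correlation.

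In all, camera called 12 of the 27 lists, 7 higher and 5 lower, while 0 were called with an estimated correlation or by fry. With the block 13 were called, and 0 with the block and an estimated correlation. The added list was macrophage identity (lower, adjusted p = 0.0491, adjusted p = 0.373 with an estimated correlation, though 19 of 34 members were higher without the block and the median was 0.01). Adjusted over the list alone, 2 members passed without the block, Lyz1 and Lyz2 in the macrophage identity list (adjusted p = 0.00602 each), and 0 members of any list passed over all genes tested. With the block, adjusted over the list alone, members of further lists passed too, among them 8 stromal genes, 6 interferon genes and 3 neutrophil genes that rose, and 5 reported ELAVL1 targets (Nos2, Ptgs2, Vegfa, Plau and Dusp1) and 4 cytokine genes (Cxcl2, Nos2, Ptgs2 and Tnfaip3) that fell. Mmp9, also a reported ELAVL1 target, rose. Lists that were not called held such members too. In angiogenesis and matrix remodelling 5 rose and 5 fell, in alternative activation 1 rose and 4 fell, and in LXR and lipid efflux 3 fell. The count of called lists was 4 without WT 1, 5 without WT 2, 5 without KO 3 and 6 without KO 4.

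In the small RNA libraries, miR-143-3p and miR-126-3p stood out among miRNAs higher in those labelled knockout. Per the sample records wild type is numbers 1 and 2 here and knockout is numbers 3 and 4, though the file of KO 4 also names KO 2. Genotype is therefore confounded with the difference between those number sets. The mRNA libraries part by these sets, and the stromal list and the Y-linked genes, which mark male cells, differ between them. Of 369 miRNAs edgeR called 22, 18 higher and 4 lower in knockout. miR-143-3p, known from smooth muscle and stromal cells, rose from 34.6 ± 34 CPM (SD, n = 2) to 166 ± 25 CPM, a log2 fold change of 2.26 (SE 0.29, adjusted p = 1.0e-11). The endothelial miR-126-3p rose from 180 ± 18 to 472 ± 72.9 CPM (log2 fold change 1.39, adjusted p = 1.1e-05). miR-541-5p at 2.30, miR-224-5p at 2.24, miR-143-5p at 1.96 and miR-379-5p at 1.79 also rose, all from under 1 CPM. The 4 that fell were miR-30c-1-3p by 1.26, miR-421-3p by 0.99, miR-671-5p by 0.91 and miR-5117-3p by 0.76.

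Of the miRNAs to be named whatever the result, those of macrophages and the let-7 family among them, only miR-9-5p passed the test with all 4 libraries, in the same comparison of numbers and labels, and 5 others passed without 1 library. miR-21a-5p took 46.7%, 45.6%, 50.5% and 45.6% of counts in WT 1, WT 2, KO 3 and KO 4, a log2 fold change of 0.15 (SE 0.17, adjusted p = 0.801). miR-27a-3p had a log2 fold change of -0.06 (SE 0.20) and miR-27b-3p of 0.08 (SE 0.20). The values were 0.23 for miR-155-5p, 0.20 for miR-223-3p, -0.21 for miR-146a-5p, 0.28 for miR-16-5p and -0.36 for miR-7a-5p. With 1 library left out, miR-155-5p ranged from 0.035 to 0.41 and miR-16-5p from 0.092 to 0.46. The ranges were -0.36 to -0.058 for miR-146a-5p and -0.56 to -0.17 for miR-7a-5p. miR-142-3p, at 7828 ± 1472 and 11511 ± 1613 CPM, had 0.56 (SE 0.20, adjusted p = 0.0770). miR-21a-5p passed without KO 4 (0.29, adjusted p = 3.5e-09), miR-146a-5p without KO 3 (-0.36, adjusted p = 0.00023) and miR-142-3p without KO 3 (0.40, adjusted p = 0.0254) and without KO 4 (0.71, adjusted p = 6.2e-07), fits in which the arm with 1 sample is assumed to vary like the other. miR-9-5p passed (1.64, SE 0.55, adjusted p = 0.0450) at 0.918 and 2.85 CPM, and its adjusted p was 0.404 without WT 1, 0.291 without WT 2, 0.0877 without KO 3 and 0.487 without KO 4. Of 14 let-7 and miR-98 species 0 passed, with a median of -0.01 and a range from -0.49 to 0.40, and 9 of the 14 changed sign under some other scaling, filter or left-out library. let-7e-5p passed without KO 3 (-0.50, adjusted p = 0.0481) and let-7g-5p without KO 4 (0.53, adjusted p = 0.00383). Of 31 tested miRNAs with reported ELAVL1 effects 1 rose and 0 fell (median 0.03).

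The miRNA calls rested on few libraries. Without WT 1 edgeR called 0 (27 at an unadjusted p under 0.05), and without WT 2, KO 3 and KO 4 it called 18, 23 and 15. miR-143-3p had a log2 fold change of 1.5 without WT 1 (edgeR adjusted p = 0.0693) and 3.97 without WT 2, and DESeq2 gave it an adjusted p of 0.319. Without 1 library miR-224-5p ranged from 1.34 to 4.53 and miR-143-5p from 1.11 to 3.93, and miR-421-3p had 0.0862 without WT 1. The other miRNAs that fell were nearer no change without WT 1, with miR-30c-1-3p at -0.63, miR-671-5p at -0.49 and miR-5117-3p at -0.35. The calls of miR-541-5p, miR-379-5p and miR-9-5p ended without any 1 of the 4 libraries. Scaling to the library total called 4, all higher (100% against 81.8% of calls higher with TMM), RLE scaling called 15 with 73.3% higher, and DESeq2 called 2, miR-126-3p and miR-199b-3p.

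AGO2 groups in the library labelled knockout were more numerous, less often held a conversion and lay less often in 3′ UTRs. They were also shorter, with a median of 18 nt against 21 nt in wild type, and 29.5% of their bases were T against 31.7%. Shorter groups with less T have fewer places for a conversion or a seed match, and how much this adds was not tested. The knockout list was 1.29 times as long (95% interval 1.27 to 1.30, counting error) with 1.03 times the group reads. Groups with no conversion made up 60% (59.7 to 60.4) in knockout and 41.1% (40.7 to 41.5) in wild type. The 3′ UTR share was 20.4% (20.1 to 20.7) in knockout and 33.3% (32.9 to 33.6) in wild type, and the intergenic share was 50% (49.6 to 50.3) and 35.2% (34.8 to 35.6). Among groups with at least 1 conversion the ratio of knockout to wild type numbers turned to 0.872 (0.860 to 0.885), and in 3′ UTRs with a conversion it was 0.740 (0.725 to 0.757). With 1 library per genotype there is no replicate check, and these intervals compare the libraries, not the genotypes.

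**Figure D2:**
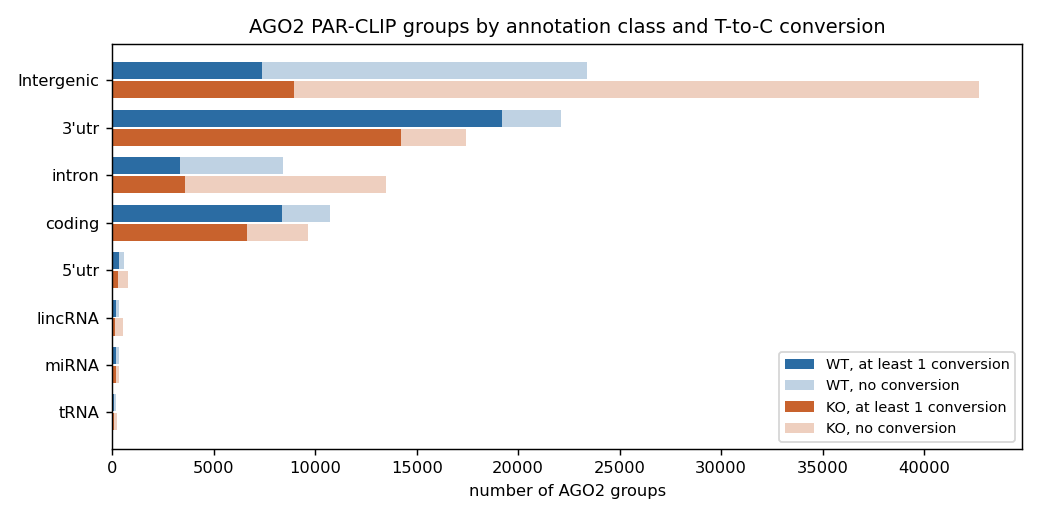
Number of AGO2 groups (x axis) in the 8 most frequent annotation classes (y axis) for the wild type and knockout libraries, split into groups with and without a T-to-C conversion. The 42709 intergenic groups in knockout and 23393 in wild type differ mostly in groups without a conversion, while 3′ UTR groups number 17420 and 22109.

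Groups with many reads were mostly shared by the libraries. Of wild type groups 41.0% (40.6 to 41.3) were overlapped by a knockout group by at least 1 nt on the same strand, and of knockout groups 32.0% (31.7 to 32.3) by a wild type group. Among wild type groups with at least 50 reads the share was 90.7% (90.1 to 91.3). In 3′ UTR groups 40.7% (40 to 41.3) of wild type and 52.1% (51.4 to 52.9) of knockout groups were shared.

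The most read genes were nearly the same in both libraries. Vmp1 led with 195983 wild type and 365891 knockout reads, almost all in 1 3′ UTR group on chromosome 11 (86397618 to 86397644 in wild type) whose sequence holds that of miR-21a-5p, which lies at the end of that gene. Spred1, a Ras pathway inhibitor, had 40033 and 25685 reads, most in a 3′ UTR group on chromosome 2 (117005250 to 117005287 in wild type). The lysosomal gene Psap had 39381 and 27188 reads, the elongation factor gene Ell2 35509 and 21243 and the immediate early gene Fos 32081 and 27274, each led by a 3′ UTR group. Rgs7 was among the top 5 in knockout only, with 25843 reads against 8231, in an intron group on chromosome 1 (177149609 to 177149627 in knockout) with 28 conversion events.

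The largest rises in group reads were in genes with no wild type group listed, so no fold is given. Rimbp2 had 368 knockout reads, Il22ra2 317, Srpx 157 and Mylk 156, each led by an intron group, and N28178 had 1 intron group (42940510 to 42940527 on chromosome 4). The largest falls were in genes with no knockout group listed, at 269 wild type reads for Pomt1, 202 for 1700066M21Rik, 176 for Nol7, 161 for Bod1l and 136 for Slfn9. All but Pomt1, led by a coding group, were led by a 3′ UTR group.

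Zfp36 carried strong AGO2 sites in both libraries. Its groups held 2793 reads in 14 groups in wild type and 3413 reads in 19 groups in knockout. The main group lay in its 3′ UTR on the minus strand of chromosome 7 (29162126 to 29162210 in wild type, 29162126 to 29162208 in knockout) with 1606 wild type and 2178 knockout reads and a miR-27 seed match. Its wild type sequence was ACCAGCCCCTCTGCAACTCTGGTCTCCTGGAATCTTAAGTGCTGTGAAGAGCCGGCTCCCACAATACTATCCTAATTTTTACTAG. A second 3′ UTR group at 29162421 to 29162453 with miR-25/92 and miR-29 matches had 479 and 554 reads. Elavl1 itself had 114 wild type and 138 knockout reads in 4 groups each, with 75 and 59 reads in a 3′ UTR group on the minus strand of chromosome 8 (4289403 to 4289426) without a match to a listed seed.

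Sites in both libraries matched the seeds of macrophage miRNAs well above shuffled sequence. A 7mer to any of the 30 listed families stood in 20.8% (20.5 to 21.1) of wild type groups and 15.1% (14.9 to 15.4) of knockout groups, against 7.44% and 6.09% after shuffling. The 9 control families matched 1.73% and 1.37%, against 1.73% and 1.43% after shuffling. Among 3′ UTR groups with a conversion the order turned, with 30.2% (29.5 to 30.8) in wild type and 31.3% (30.5 to 32.1) in knockout.

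miR-27 had the highest share of any family, at 2.71% (2.59 to 2.84) of wild type and 2.05% (1.96 to 2.15) of knockout groups, 6.96 and 5.67 times the shuffled share. In converted 3′ UTR groups its shares were 3.27% (3.02 to 3.53) and 3.59% (3.29 to 3.91). miR-15/16 came next there with 2.58% (2.36 to 2.81) and 2.72% (2.45 to 3), then miR-29 with 1.98% (1.79 to 2.19) and 2.19% (1.96 to 2.45). The family of miR-221 and miR-222 stood furthest above shuffled sequence over all groups, 8.98 times in wild type and 8.58 times in knockout. The miR-155 and miR-9 seeds, at 0.157% each in wild type, were 1.08 and 1.16 times their shuffled shares.

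**Figure D3:**
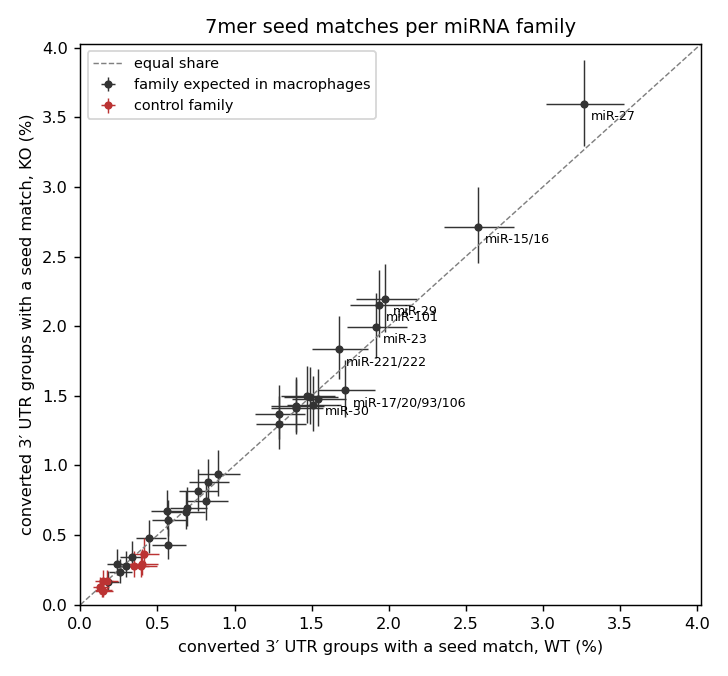
Share of converted 3′ UTR groups with a 7mer seed match for each miRNA family in the wild type library (x axis, percent) and the knockout library (y axis, percent). Points are families, error bars are exact 95% intervals for counting error and the dashed line marks equal shares. miR-27 stands highest in both at 3.27% and 3.59%.

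Genes with AGO2 groups in their 3′ UTR showed mRNA changes close to 0. Of genes with 3′ UTR groups in both libraries 4545 were tested and 2342 were lower in the mRNA libraries labelled knockout, with a median log2 fold change of -0.01. The 755 genes with groups in knockout only and the 1261 with groups in wild type only also had medians of -0.01. Camera called 0 of the 3 sets (adjusted p = 0.83 each, unadjusted p at least 0.338), and 1 with an estimated correlation, the wild type only set (lower, adjusted p = 0.0444), which was not called with the block and an estimated correlation (adjusted p = 0.228). Against random lists matched on expression the medians lay at percentiles 0, 26.9 and 2.21, so the set in both libraries lay below all 10000 of its random lists, whose medians had a 95% range of 0.00355 to 0.0102. Random lists do not keep the correlation between genes of a set, so the percentiles do not measure a genotype difference. Across 3935 genes, which are not independent, the change in group reads and the mRNA change had a Spearman correlation of 0.0664.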

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

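Of the tests below, those of library depth, crosslinking, 3′ UTR sites, swapped labels and the floxed exon, the splits counted for genes and the need for an estimated correlation in the stromal test, were chosen after the result was seen.

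In 6 of 78 groups of 4 libraries 1 library stood far from the other members, and chance gives about 1 in 20. Zfp36 had 194 CPM in WT 4 against at most 139 in the other wild type libraries. In KO 1 Tnf had 99.6 CPM against at most 60.4 in the other knockout libraries, Mmp9 had 118 against at most 28.8, and Cxcl2 had 6.37 against at most 1.92. The mean log2 CPM of the alternative activation list was 4.52 in KO 1 against at least 5.41 in the other knockout libraries, and that of the lysosome list was 8.50 in WT 1 against at least 8.86 in the other wild type libraries. The library of the same number stood at the same end in the other genotype, with Tnf, Mmp9 and Cxcl2 highest in WT 1 (95.2, 58.5 and 18.1 CPM), Zfp36 highest in KO 4 (253 CPM), alternative activation lowest in WT 1 (4.50) and lysosome lowest in KO 1 (8.59).

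AGO2 groups were 1.29 times as many in the library labelled knockout. More depth alone would also add groups with a conversion, and these stood at 0.872 of the wild type number, but full library depth is not given in the sources used here and a part in the excess stays open. More crosslinked 3′ UTR sites do not account for it, since converted 3′ UTR groups stood at 0.740. More uncrosslinked background in the knockout library remains a candidate explanation, because with 0.872 as many converted groups those without a conversion hold the whole excess. Knockout groups were also shorter, with a median of 18 nt against 21 nt in wild type. A short group can lack a conversion although crosslinked, and this was not tested. With 1 library per genotype a preparation difference and a loss of ELAVL1 are confounded.

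Lyz1 was lower together with Lyz2 while Elavl1 was not. LysM-Cre, placed in the Lyz2 gene, goes with the knockout label. A lower Lyz2 could come from that insertion and does not show a loss of ELAVL1. Swapped genotype labels are argued against, since the highest knockout Lyz2 level was 6142 CPM and the lowest wild type level 9949. Reads shared between the lysozyme copies may explain the Lyz1 part. The spread of their log2 ratio over all mRNA libraries was 0.141 of the spread of Lyz2 itself. This cannot decide it, since log2 fold changes as alike as -1.28 and -1.29 make the ratio small with or without shared reads. Neighbouring genes regulated together would give the same ratio. Elavl1 transcripts that lack the floxed exon could still be counted over the whole gene (log2 fold change 0.13), and without exon counts this cannot be told apart from incomplete deletion.

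miR-143-3p and miR-126-3p, known from stromal and endothelial cells, were higher in small RNA libraries labelled knockout, which are also numbers 3 and 4. A different share of stromal cells in numbers 3 and 4 is a candidate source. The fibroblast or stromal list had a median log2 difference of 3.44 between the mRNA libraries of numbers 3 and 4 and of 1 and 2. Bgn and Col1a1 stood at 4.95 and 2.59 CPM on average in wild type, and Lox, at 237 CPM, went the other way. The endothelial list had a median of 0.67 with 5 of 8 genes higher and was not called (camera adjusted p = 0.133). For endothelial cells this source therefore has no called list behind it. The stromal list was also called higher with the knockout label in the blocked fit (camera adjusted p = 9.6e-05), which met the prediction written beforehand, but not with an estimated correlation (adjusted p = 0.395), a condition added after the values were seen. In the fit without the block its direction was lower without KO 4 (camera adjusted p = 0.846), but leaving out a library there also unbalances the number sets. No blocked fit of the lists left out a pair. Within each number set its call was lost with an estimated correlation (camera adjusted p = 0.863 in 1 and 2, 0.503 in 3 and 4). Number and genotype therefore cannot be told apart for these miRNAs.

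Splits of the 8 mRNA libraries into sets of 4 do not exclude chance for the lists called without the block. For genes the splits decide nothing, since the real count of 0 is reached by all 35 of them. The highest other, 7371 genes, was the split of numbers 1 and 2 from numbers 3 and 4, which points to a structure of the samples. As many lists as the real 12 were called in 6 of 35 splits, with 13 as the highest other. Among the 8 splits that part all pairs the highest other called 8 lists. For the AGO2 gene sets the real 0 is likewise reached by all 35 and decides nothing, and the highest other called 1. With the block the real split called 5 genes and the highest of the other splits that part all pairs called 0, and these 8 splits are too few for a share under 0.05.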

How the results depend on the processing

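Chosen after the result was seen were the fits within numbers 1 and 2 or 3 and 4 or with those sets as a block, blocked fits without a pair, with DESeq2, with a fold minimum or with an estimated correlation, RLE scaling of miRNAs, the classes with at least 1 conversion, and 3′ UTR groups for group numbers and overlap. The class with at least 2 conversion locations and 3′ UTR groups for seeds were planned.

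The count of mRNA genes, 0 without the block, was also 0 with RLE scaling, with other filters, with a fold minimum and without any 1 library (range 0 to 0). It was 5 with the replicate block and also with the block and a fold minimum, 3 with DESeq2, 82 with the block and DESeq2, 1 with a block of number sets and 14 with numbers 3 and 4 alone. Without pairs 1 to 4 the blocked counts were 4, 29, 7 and 3. Elavl1 ranged from 0.08 to 0.17 without 1 library and passed in no fit. Lists called fell from 12 to 0 with an estimated correlation, to 0 with fry, to 0 with the block or either number set and an estimated correlation and to 5 with numbers 1 and 2 alone, and ranged from 4 to 16 without 1 library. Called AGO2 gene sets went from 0 to 1 with an estimated correlation and stayed at 0 to 0 without any 1 library.

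Called miRNAs went from 22 to 4 with the library total, 11 with the stricter filter and 2 with DESeq2, and ranged from 0 to 23 without 1 library, where the lone sample of an arm is assumed to vary like the other arm. No paired analysis was possible for miRNAs because no number is shared as the sample records label them (the file of KO 4 names KO 2 over its fractions).

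The ratio of AGO2 group numbers, 1.29, turned to 0.642 with at least 2 conversion locations, 0.872 with a conversion, 0.788 in 3′ UTRs and 0.740 in converted 3′ UTR groups, and was 1.27 after thinning to equal group reads. Shared wild type groups, 41.0%, moved to 39.6% at 50% coverage, 46.9% at 10 reads, 90.7% at 50 reads, 38.5% with equal numbers of top groups, 43.9% with 33225 top groups and 35.5% with a conversion in both. The knockout to wild type ratio of seed match shares, 0.727, was 0.763 at 10 reads, 0.707 for 8mers, 0.765 for 6mers and 0.915 with a conversion, and turned to 1.01 in 3′ UTRs and 1.04 in converted 3′ UTR groups.

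Of named results that had not passed, Tnf turned positive with numbers 1 and 2 alone (0.10), in the block without pair 3 (0.0236) and without WT 1 or KO 3 (range -0.32 to 0.0920), Mmp9 ranged from -0.16 (without KO 1) to 1.93, miR-21a-5p from -0.00434 to 0.29 and miR-223-3p from -0.0531 to 0.42 (both lowest without KO 3), and miR-27b-3p was -0.000308 with the library total. miR-421-3p, which had passed, ranged from -1.71 to 0.0862 (highest without WT 1). The let-7 and miR-98 species were summed to a count of calls, 0 in the main comparison and up to 1 without 1 library, after it was seen that 9 of 14 changed sign. The other named values kept their direction, with 161 mRNA and 114 miRNA values on the same side of the threshold, 35 and 6 newly past it and 0 and 44 no longer past it. The cause was not tested. DESeq2 gave no adjusted p for 9 miRNA values, which are left out. Pseudocounts and quantile or upper quartile scaling were not run, since the values are counts. In simulated data the mRNA test without the block called 8.96% of genes changed 2-fold.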

Other observations

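Of the observations here, all were chosen after the result was seen except the gene lists, which were fixed.

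Transcripts of the Y chromosome split the mRNA libraries by number. Ddx3y, an RNA helicase gene, stood at 38.1, 24.5, 24.8 and 24.3 CPM in WT 1, WT 2, KO 1 and KO 2 and at no more than 0.0860 CPM in WT 3, WT 4, KO 3 and KO 4. Kdm5d stood at 25.7, 19.8, 22.8 and 20.8 CPM in the same numbers 1 and 2 and was at 0 in numbers 3 and 4, as was Eif2s3y after 18.6, 16.9, 17.5 and 20.4 CPM. Numbers 1 and 2 thus had the Y transcripts of male cells, and numbers 3 and 4 nearly lacked them, as female cells do. The sample values used here give no sex. The small RNA libraries labelled wild type carry numbers 1 and 2 and those labelled knockout numbers 3 and 4. If the numbers mean the same donors there, that comparison also sets male wild type against female knockout cells.

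Numbers 3 and 4 also differed from numbers 1 and 2 in other fixed lists. Angiogenesis and matrix genes had a median log2 difference of 1.10, with 22 of 28 higher (camera adjusted p = 2.9e-06, adjusted p = 0.466 with an estimated correlation). MHC class II antigen presentation genes had 1.08, with 11 of 13 higher (camera adjusted p = 0.00404, adjusted p = 0.652 with an estimated correlation), and LXR and lipid efflux genes 0.44, with 16 of 22 higher (camera adjusted p = 0.00197, adjusted p = 0.466 with an estimated correlation). T or NK lymphocyte markers had 1.21, with 4 of 4 higher (camera adjusted p = 0.0103). Mast cell or basophil markers had 1.71, with 5 of 5 higher (camera adjusted p = 0.0207). With an estimated correlation the adjusted p of both marker lists was 0.466.

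Between genotypes the other 15 fixed lists were not called without the block. The adjusted p was 0.221 for macrophage identity and for angiogenesis and matrix remodelling, 0.409 for erythroid markers, 0.472 for the miRNA pathway, chemokine receptors and osteoclast markers, 0.564 for cholesterol synthesis and 0.602 for apoptosis and dendritic cell markers. It was 0.939 for regulators of mRNA decay and B lymphocyte markers, 0.964 for T or NK markers and 0.979 for alternative activation, LXR and lipid efflux and MHC class II. The median and the test differed in sign for alternative activation, LXR, MHC class II, macrophage identity and the B, T or NK and osteoclast markers.

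Groups holding miRNA sequences took part of the AGO2 group reads, given here as shares of all group reads, whereas small RNA shares are of miRNA counts only. The bases, libraries and protocols differ, so the shares do not compare directly. Groups holding the core that miR-27a-3p and miR-27b-3p share took 14.5% of wild type and 12.4% of knockout group reads. In WT 1, WT 2, KO 3 and KO 4 miR-27a-3p took 0.575%, 0.574%, 0.512% and 0.531% of small RNA counts and miR-27b-3p 1.18%, 1.21%, 1.18% and 1.21%. miR-21a-5p took 3.08% and 5.68% of group reads, against 46.7%, 45.6%, 50.5% and 45.6% of small RNA counts in the same order. miR-142-3p took 4.53% and 1.77% against 0.692%, 0.922%, 1.18% and 1.05%, and miR-223-3p 2.12% and 1.40% against 0.0315%, 0.0379%, 0.0414% and 0.0331%. The core shared by let-7a-5p and let-7c-5p took 0.0338% and 0.0181% of group reads, against 5.94%, 5.19%, 5.74% and 5.30% for let-7a-5p and 9.72%, 9.94%, 8.45% and 10.2% for let-7c-5p. That core lay in 4 wild type and 3 knockout groups. How reads that map more than once were treated is not given, so a low share need not mean little AGO2 binding. let-7g-5p took 1.32% and 1.5% against 0.489%, 0.502%, 0.638% and 0.470%, and miR-155-5p 0.0408% and 0.0431% against 0.0351%, 0.0376%, 0.0431% and 0.0369%.

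In converted 3′ UTR groups, sites listed in both libraries held a match to a listed seed in 41.6% (40.5 to 42.7) of wild type groups, against 21.4% (20.7 to 22.2) of those in wild type alone. The knockout shares were 40% (38.9 to 41) and 20% (19 to 21). Shared groups were also longer and had more reads in both libraries, with medians of 27 against 24 nt and 37 against 15 reads in wild type and 26 against 24 nt and 33 against 17 reads in knockout.

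A cluster of groups annotated as intergenic on chromosome 17 (39980042 to 39985774 in wild type) held 6.57% of wild type and 3.34% of knockout group reads. It comprised 66 and 60 groups and held 29.8% of wild type and 12.2% of knockout reads in intergenic groups. The annotation could not be checked, and which RNA these reads come from was not tested.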
